A study of Homo sapiens with 4 samples.

How the data were processed

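Total RNA from Caco-2 and HCT116 cells, both established colorectal cancer lines, was measured on 4 Affymetrix PrimeView arrays, 1 for each combination of cell line and siRNA. Per the labels' protocols, cells were transfected with BORIS siRNA for 3 days, RNA was extracted with TRIzol, and biotin-labelled cRNA was made with a 3' in vitro transcription kit. The deposited values are log2 expression values per probe set: the unit follows from their range of 2.13 to 14.17, and the quartiles of the 4 arrays lie within 0.129 of each other. The background correction, normalization and summarisation the authors used are not given in the sources used here. No scanner files were used here, and the siRNA sequences are not given in the sources used here. Genes were not centred, and no column of another sample was present.

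Probe sets were named through the platform's annotation table. Of 49395 probe sets, 44988 were paired with 1 gene, 1832 with several genes, 2569 were not listed in the table, and 6 were control probe sets that the table pairs with 1 gene, not used for genes. Control probe sets numbered 102. Symbols were looked up by Entrez ID in a RefSeq gene table of assembly GRCh38.p14, which changed 0 of them. That table also gave genomic gene lengths, and no coordinates are reported because the array names no build. A gene was represented by the probe set with the highest mean over the 4 arrays among those paired with it alone, which gave 18132 genes. Probe sets of the _x_at and _s_at kinds can bind related transcripts. With these left out, some named genes have no value, among them CTCF, ORM2, APOBEC3B, TUBA1A, HGD, TRIAP1, BEX3, OASL, SRXN1, TM7SF2, ATP5MC1, SCD, CLDN4, ELF3, ID2 and ACTB.

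The choices below were made before the data were examined unless stated otherwise. Within each line, the difference between siRNAs was the log2 value with BORIS siRNA minus that with control siRNA. Expressed genes at 2-fold or more, a log2 difference of 1, were counted, with no test because each group holds 1 array. A value below the 95th percentile of olfactory receptor probe sets of its array counted as at background, and a difference from it was given as a lower bound against that level (means over the arrays of a line for the line difference), a choice made after the data had been seen. Genes at background on all compared arrays were given no fold. An effect shared by both lines was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on all 4 arrays with cell line as a block, at a Benjamini-Hochberg adjusted p under 0.05. The residual spread of that fit is the disagreement between the lines. The line difference came from the same fit, with siRNA as the block. The labels give no replicate numbers, so no other pairing exists.

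Gene lists were described by the median difference of their expressed members, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart in the lowest or highest 2.5% of random lists, and lists with fewer than 5 expressed members were given no percentile. Percentiles describe these arrays and are not p-values. Genes named in the text were CTCFL and CTCF, the 10 expressed genes per direction with the largest difference at 2-fold or more in each line, the 10 per direction with the largest smaller-of-2 difference shared by both lines, the 10 per direction with the largest line difference past the test, and members of the lists drawn from the up to 4 with the largest difference. Genes at 2-fold or more in opposite directions, and genes past the limma test for siRNA, would also have been named, but there were 0 of each.

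The methods were tested on simulated data. In 10 simulated sets of 11165 genes with the variances of the limma fit, 200 genes were changed equally in both lines. Of these, 100 were changed 2-fold and 100 were changed 4-fold. The test of the shared effect recovered on average 46.9% of 2-fold changes, between 19 and 72% per set, and 97.2% of 4-fold changes, between 94 and 100%. The 2-fold genes were adjusted together with the 4-fold genes, so 46.9% does not give the recovery on arrays without such larger shared changes. Unchanged genes made up 12.2% of the calls of the test over the 10 sets, above the nominal 5%, and numbered 2 to 51 per set. The prior degrees of freedom were 5.49 in the simulation and were estimated at 4.74 to 15.36. Calls of the shared effect are therefore more liberal than their adjusted p states; the line difference was not simulated. Of 40 simulated unchanged lists of 30 genes, 0 stood apart, and 40 of 40 did after a shift of 0.5. The simulated genes varied independently of each other, so lists whose members vary together were not tested.

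Alternatives were no filter on dim probe sets, a filter at the 95th percentile of olfactory receptor probe sets, the mean of all probe sets of a gene, leaving out _x_at and _s_at probe sets, quantile normalization, a loess correction on mean expression (fraction 0.3) within each line, adding 16 on the linear scale before log2, 1.5-fold and 3-fold, eBayes without trend, no cell line block, and random lists without matching. Some alternatives were added after the data had been seen. They were keeping only genes whose bright probe sets share a direction, and raising values at background to the background level. A further one was leaving out genes whose difference between siRNAs had the same value in both lines. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.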

Results

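Gene expression was measured after RNA interference against BORIS in 2 human colorectal cancer cell lines, Caco-2 and HCT116. BORIS is the protein of CTCFL, a paralog of the chromatin insulator protein CTCF that is normally made in the testis and in some tumours. Each line received BORIS siRNA or a negative control siRNA for 3 days, and total RNA from each of the 4 samples was hybridised to 1 PrimeView array, so every group held 1 array. The table gave a log2 value for 49395 probe sets per array, with array medians between 5.46 and 5.48. A gene counted as expressed in a line when its probe set reached the median of all probe sets on at least 1 of the 2 arrays of that line, which gave 10389 genes in Caco-2 and 10631 in HCT116. The 95th percentile of olfactory receptor probe sets on an array, 4.80 to 5.15, was taken as background, and where the dimmer value lay below it the difference is given as at least the distance of the brighter value from that level, on the log2 scale. With 1 array per group, differences between siRNAs within a line have no replicate check and no p-value, and the number of arrays limits the precision.

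The targeted gene was examined first. CTCFL was represented by 7 probe sets, and none of them reached the array median on any array. Of these, 1 lay above background on both Caco-2 arrays, at 5.07 with control siRNA and 5.09 with BORIS siRNA, a difference of 0.02, and below it on both HCT116 arrays. The other 6 lay below background on all 4 arrays and have no fold. The extent of the knockdown could therefore not be measured on these arrays, and the siRNA labels have no check from the target. CTCF differed by -0.03 in Caco-2 and -0.33 in HCT116.

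**Figure D1:**
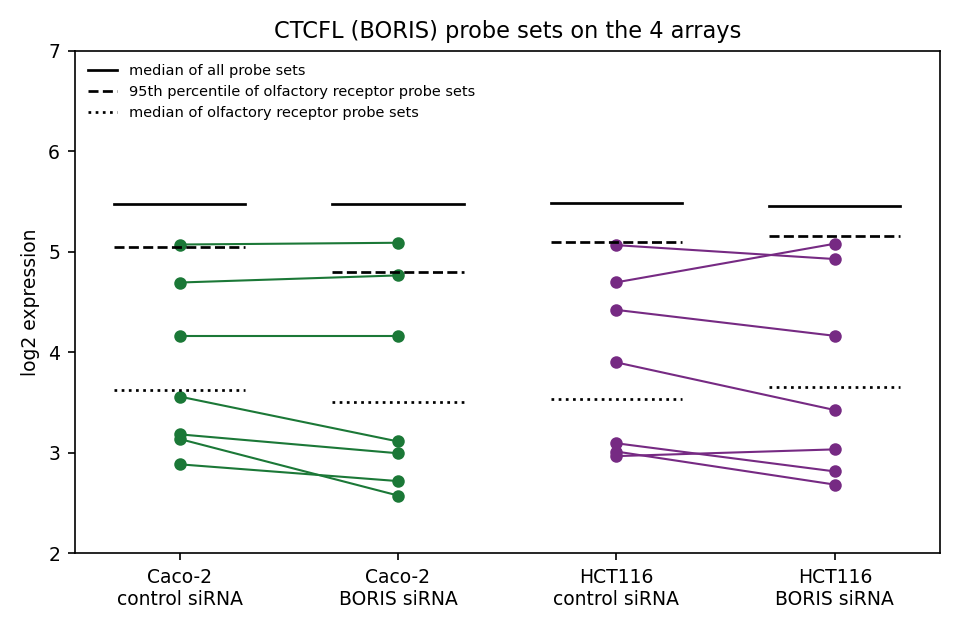
Log2 expression of the 7 CTCFL probe sets (points, joined within a cell line) on the 4 arrays, with the median of all probe sets (solid line) and the 95th percentile and median of olfactory receptor probe sets (dashed and dotted lines). No CTCFL point reaches a solid line, and the highest lies at 5.09.

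The first comparison asked which genes differed between BORIS siRNA and control siRNA in Caco-2. At 2-fold or more, 42 expressed genes were higher and 5 lower with BORIS siRNA, and 29 and 4 with values at background raised to that level. TCN1, a vitamin B-binding carrier protein, was higher by 1.98, the zinc finger gene ZNF615 by 1.60, the tubulin gene TUBA1A by 1.56, the cornified envelope gene SPRR1B by 1.54 and the glycosyltransferase gene B3GNT7 by 1.47. For genes at background with control siRNA, the difference was at least 1.35 for TRIM29, 1.18 for the monocarboxylate transporter gene SLC16A12, 0.97 for VCAN, the extracellular matrix proteoglycan versican, 0.93 for the zinc finger gene ZNF681 and 0.90 for the integrin gene ITGA1. The 5 lower genes were ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, at -1.41, HGD, an enzyme of tyrosine breakdown, at -1.21, REG4 at -1.12, the matrilin gene MATN3 at -1.01 and LHFPL3, at background with BORIS siRNA and lower by at least 0.72. As means over their probe sets, VCAN and ZNF615 each stood at 1.04, B3GNT7 at 0.84 and TRIM29 at 0.68, and VCAN stood at 0.89 with probe sets of the _x_at and _s_at kinds left out, where TUBA1A and HGD have no value. With such means for every gene, 22 genes were higher and 5 lower.

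Of 37 gene lists fixed before the data were examined, 33 had at least 5 expressed members in Caco-2, and 7 of these stood apart from random lists matched on expression. Lists of genes that vary independently would give 1.65 by chance. Members of a list can vary together between 2 arrays, so the excess over 1.65 cannot be told apart from such variation. Interferon-stimulated genes were lower, with a median of -0.20 and 19 of 29 members lower (percentile 0.0), among them OASL at -0.82, ISG20 at -0.55 and IFIT1 at -0.30. Genes of the NRF2 and oxidative stress response were lower in 24 of 32 cases (median -0.11, percentile 0.01), with the heme oxygenase gene HMOX1 at -0.83 and SRXN1 at -0.56, and SLC7A11 at 0.33. Enterocyte differentiation genes had a median of -0.14 with 11 of 17 lower (percentile 1.08). REG4, MUC13 at -0.86 and CA2 at -0.66 were lower in that list, and the glucose transporter gene SLC2A2 was higher by 0.76. Cholesterol synthesis genes were higher in 16 of 20 cases (median 0.15, percentile 99.16), with TM7SF2 at 0.62 and HMGCS1 at 0.56. Chromatin and DNA methylation regulators were higher in 29 of 39 cases (median 0.15, percentile 99.98), although DNMT1 at -0.06 and KMT2B at -0.10 differed little. Oxidative phosphorylation genes had a median of -0.071 with 32 of 46 lower (percentile 0.35), ATP5MC1 being the lowest of the named members at -0.56. MYC and ribosome biogenesis genes had a median of -0.060 with 27 of 39 lower (percentile 1.82), with RRP12 at -0.27 and NOLC1 at 0.45. In HCT116, cholesterol synthesis genes were lower in 15 of 20 cases (median -0.21, percentile 7.78, and 0.65 with the mean of all probe sets of a gene) and chromatin regulators in 28 of 39 (median -0.11, percentile 15.7). Interferon-stimulated genes were lower there in 19 of 30 cases (median -0.17, percentile 8.59), with IFIT1 at 0.76, MYC and ribosome biogenesis genes in 21 of 39 (median -0.040, percentile 34.11) and enterocyte genes in 6 of 8 (median -0.20, percentile 14.96, and a median of 0.047 without a filter). The calls for oxidative phosphorylation, MYC and enterocyte genes ended under at least 1 other setting, with percentiles up to 12.35, 10.1 and 12.2.

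The same question was asked in HCT116. More genes were lower than higher there, with 154 expressed genes lower and 62 higher at 2-fold or more, and 139 and 54 with values at background raised to that level. The acute-phase protein gene ORM2 differed by -2.12, RPL27A by -1.80, the cytidine deaminase gene APOBEC3B by -1.76 and the Mediator subunit gene MED24 by -1.72. The 1 probe set of RPL27A read 7.58 with control and 5.78 with BORIS siRNA, where the ribosomal protein gene RPL7 read 12.55 and 12.88. All 8 bright MED24 probe sets were lower. For genes at background with BORIS siRNA, the value was lower by at least 1.64 for the inhibitory SMAD gene SMAD6, 1.55 for the acute-phase protein gene ORM1, 1.17 for the syntaxin gene STX11, 1.12 for the receptor gene GPR39, 0.73 for the transcriptional repressor gene BHLHE41 and 0.35 for the Notch coactivator gene MAML3. NME5 was higher by 2.30, the small nucleolar RNA SNORA12 by 1.96, the annexin gene ANXA10 by 1.73, KRT13 by 1.62, TM4SF18 by 1.43, MED11 by 1.40 and C12orf60 by 1.31. At background with control siRNA, the small Cajal body RNA SCARNA14 was higher by at least 1.31, KRCC1 by at least 1.21 and CLHC1 by at least 0.90. The split between lower and higher genes was 126 to 98 after quantile normalization and 120 to 92 after a loess correction on mean expression, and 55 to 39 with the mean of all probe sets of a gene. With _x_at and _s_at probe sets left out, ORM1 stood at -0.07 and BHLHE41 at -0.06, and as means over probe sets STX11 stood at -0.55, MAML3 at -0.60, SMAD6 at -0.75 and CLHC1 at 0.82; ORM2 and APOBEC3B, with 1 _x_at probe set each, have no value without that kind.

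In HCT116, 8 of 34 lists stood apart, where lists of independently varying genes would give 1.7 by chance, with the same limit. Immediate early and AP-1 genes were lower in 27 of 28 cases, with a median of -0.51 (percentile 0.0), including CCN2 at -1.32, DUSP5 at -1.12 and EGR1 at -1.09. Epithelial genes were lower in 23 of 27 cases (median -0.46, percentile 0.0), with the tight junction gene CLDN4 at -0.84, OVOL1 at -0.81 and ELF3 at -0.80. Hypoxia and glycolysis genes were lower in 29 of 32 cases (median -0.35, percentile 0.0), with PFKFB4 at -1.12, ALDOC at -1.09 and the glucose transporter gene SLC2A1 at -1.05. NF-kB and cytokine genes had a median of -0.37 with 15 of 19 lower (percentile 0.17), with TNFAIP3 at -1.11 and CCL20, at background with BORIS siRNA, lower by at least 0.42. Fatty acid synthesis genes had a median of -0.39 with 14 of 17 lower (percentile 0.12), with LPIN1 at -0.77 and SCD at -0.58. WNT and intestinal stem cell genes had a median of -0.24 with 15 of 20 lower (percentile 1.17), CCND1 standing at -1.09 and DKK4, at background with control siRNA, higher by at least 0.60. NRF2 and oxidative stress genes had a median of -0.17 with 17 of 31 lower (percentile 1.32), with HMOX1 at -0.56 and GPX2, at background with control siRNA, higher by at least 0.45. Oxidative phosphorylation genes were higher in 30 of 46 cases (median 0.15, percentile 99.92), with COX7B at 0.48 and UQCRB at 0.48. TGF-beta target genes held SMAD6, SKIL, lower by at least 1.03, CCN2 and ID2 at -1.21, and 12 of 15 were lower, but the median of -0.22 lay at percentile 5.71. In Caco-2 the medians were 0.053 for immediate early, 0.040 for epithelial, 0.035 for hypoxia, -0.11 for NF-kB, 0.045 for fatty acid, -0.019 for WNT and 0.040 for TGF-beta target genes, each of which turned sign with the mean of all probe sets of a gene or after quantile normalization, and the hypoxia list stood apart at percentile 97.75 with _x_at and _s_at probe sets left out. Beside these groups, the poly-A spike-in controls were higher by 0.88 on the HCT116 array with BORIS siRNA than on its control array. The NRF2, WNT and oxidative phosphorylation calls ended under at least 1 other setting, at percentiles of 8.4, 6.4 and 91.7, and the TGF-beta list stood apart under 5 others.

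**Figure D2:**
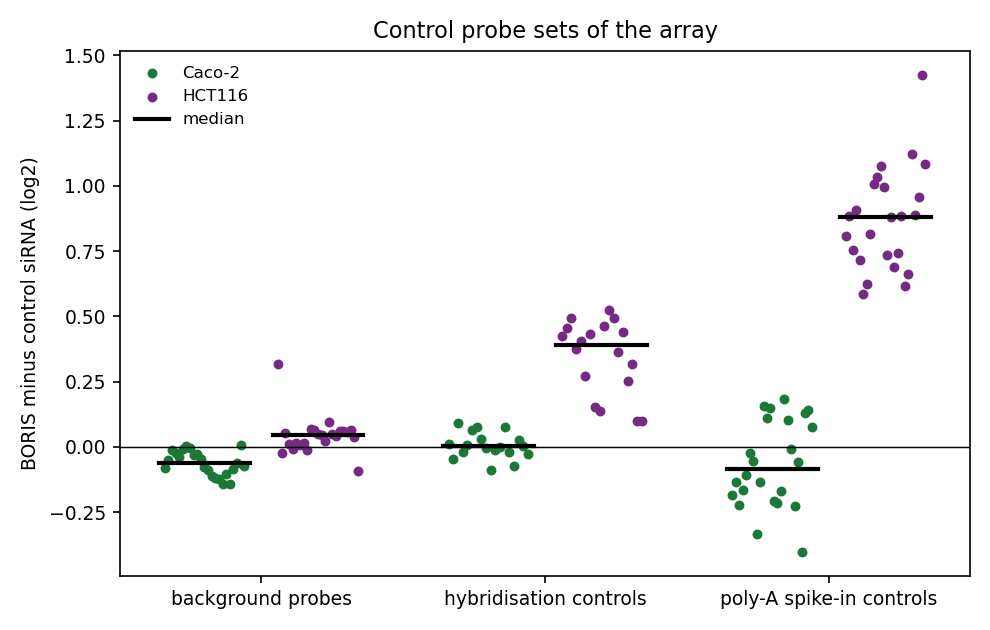
Log2 difference, BORIS minus control siRNA, of the background probes, hybridisation controls and poly-A spike-in controls of the array (points, 1 per probe set; bars, medians) in Caco-2 (green) and HCT116 (purple). All 24 poly-A spike-in controls are above 0 in HCT116, with a median of 0.88, and the Caco-2 median is -0.084.

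**Figure D3:**
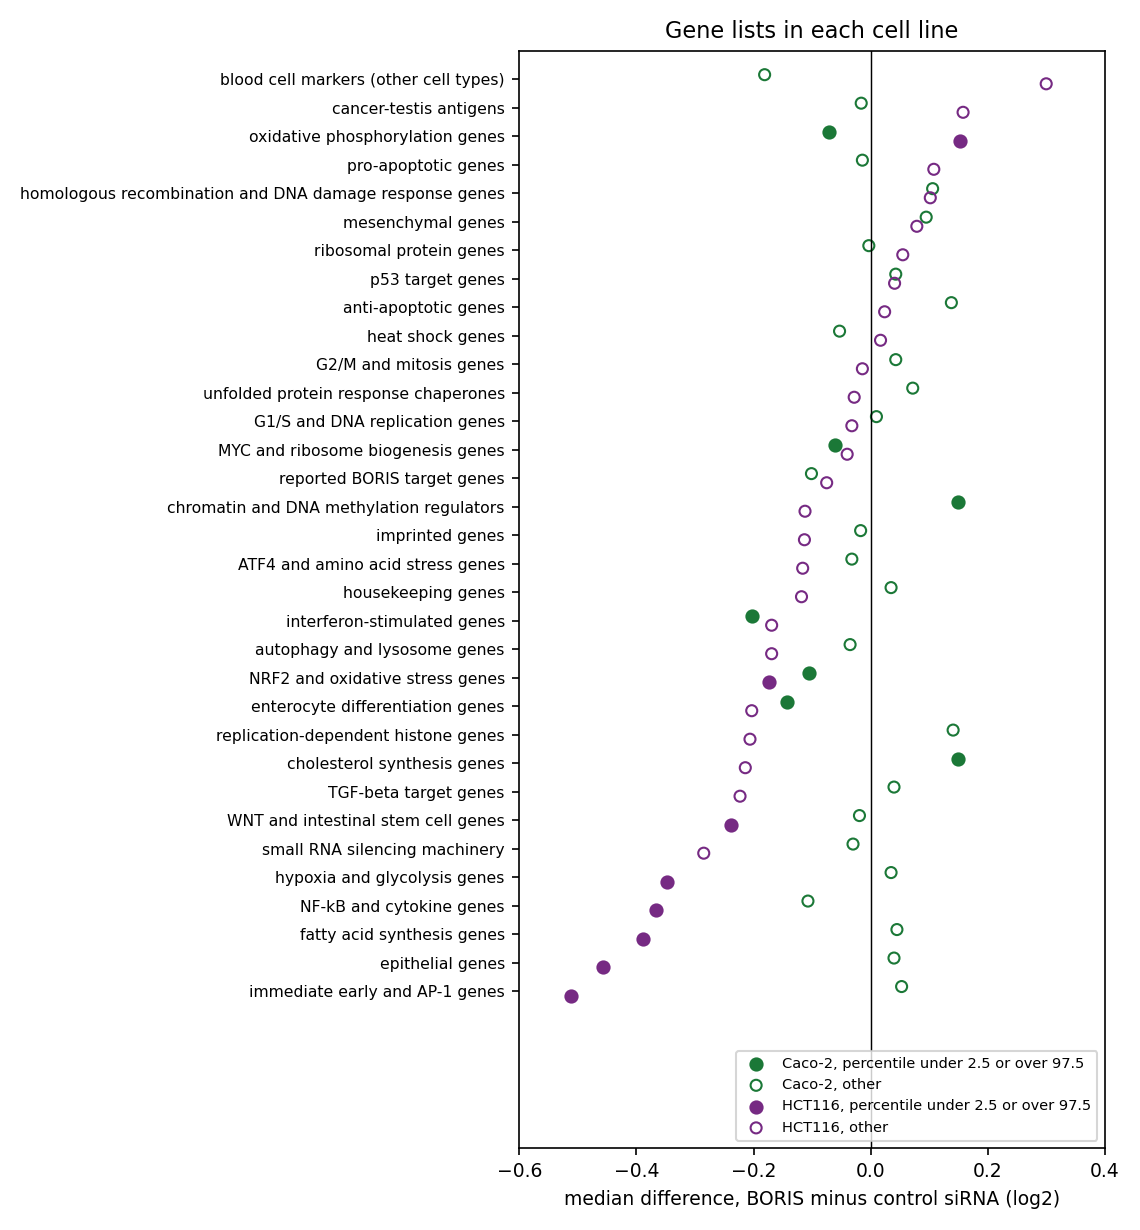
Median log2 difference, BORIS minus control siRNA, of the expressed members of each gene list (rows) with at least 5 expressed members in both lines, in Caco-2 (green) and HCT116 (purple). Filled points are medians in the lowest or highest 2.5% of random lists matched on expression. Immediate early and AP-1 genes lie lowest in HCT116, at -0.51, and at 0.053 in Caco-2, where the mean of all probe sets of a gene gives -0.011.

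The lists below did not stand apart in either line with the values as deposited. Reported BORIS target genes had medians of -0.10 in Caco-2 and -0.075 in HCT116, with ALDH1A1 and TERT at -1.41 and -0.36 in Caco-2, HMGA2 at -0.40 and -1.34 and RBL2 at 0.34 and 0.37. Of the 8 expressed members in Caco-2, 7 were lower and 1 higher (percentile 9.75), and 3 of the 6 in HCT116 were higher. Cancer-testis antigens had medians of -0.016 and 0.16, with SPA17 at 0.49 and 1.20 and PRAME at -0.65 in HCT116. Imprinted genes had medians of -0.017 and -0.11, with GRB10 at 0.75 and 0.15 and PHLDA2 at -0.12 and -0.60, and p53 target genes 0.043 and 0.041, with PLK2 at 0.97 and 0.07, PERP at 0.86 and 0.48, GDF15 at -0.25 and -0.87 and TNFRSF10D at 0.17 and -0.86. Pro-apoptotic genes had medians of -0.014 and 0.11, anti-apoptotic genes 0.14 and 0.024, and homologous recombination and DNA damage response genes 0.11 and 0.10. RAD54B stood at 0.28 and 0.82 in the last of these lists, and CLSPN, at background with BORIS siRNA, was lower by at least 1.17 in HCT116. Replication genes of the G1/S phase had medians of 0.010 and -0.032 and mitosis genes 0.043 and -0.014, with CCNE2 at 0.41 and 0.87 and UHRF1 at 0.08 and -0.54 in the first list and CENPE at -0.25 and 0.71 and FOXM1 at -0.01 and -0.68 in the second. Replication-dependent histone genes had medians of 0.14 and -0.21, ATF4 stress genes -0.032 and -0.12, unfolded protein response chaperones 0.072 and -0.028, and heat shock genes -0.053 and 0.017. Ribosomal protein genes had medians of -0.003 and 0.055, mesenchymal genes 0.095 and 0.079, autophagy and lysosome genes -0.035 and -0.17, small RNA silencing genes -0.030 and -0.29, and housekeeping genes 0.035 and -0.12. Under at least 1 other setting these medians turned sign in Caco-2 for cancer-testis (to 0.175), imprinted (0.146), p53 target (-0.059), pro-apoptotic, G1/S, ribosomal protein and housekeeping genes, and in HCT116 for p53 target (-0.079), anti-apoptotic (-0.04), G1/S, mitosis, histone (0.141 without a filter), heat shock and mesenchymal genes (-0.207). Homologous recombination and DNA damage response genes stood apart under 4 other settings in Caco-2 and 6 in HCT116, at percentiles up to 99.8 and 99.85, and at least 1 other setting did the same for BORIS target (1.15), mesenchymal (99.8), mitosis (98.45) and chaperone genes (98.6) in Caco-2, pro-apoptotic (99) and housekeeping genes (0.95) in HCT116, and histone (99.85 and 1.1) and imprinted genes (99.1 and 1.4) in both lines. Among markers of other cell types, no fibroblast marker was expressed in either line, and the blood cell markers lay at percentiles 8.92 in Caco-2 and 93.85 in HCT116. Neuronal markers lay at percentile 69.01 in HCT116, and endothelial markers, with 4 expressed members in each line, had medians of -0.17 and 0.24.

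The next comparison asked whether the 2 lines shared an effect of BORIS siRNA. XRCC4, a cofactor of the DNA end-joining ligase, was higher by 1.14 in Caco-2 and 1.15 in HCT116, and SEMA3A, a secreted guidance protein gene, by 1.25 and 1.07. They were the only 2 of 9855 genes expressed in both lines that were higher at 2-fold or more in each, where independent lists give 0.1, and 0 genes were lower in both. The chaperone gene MESD was higher by 0.92 and 0.96, TCN1 by 1.98 and 0.87, GPNMB by at least 0.57 and by 0.94 and the glucosidase gene GANAB by 0.83 and 0.82. Among zinc finger genes, ZNF572 was higher by 0.90 and at least 0.55, ZNF84 by 0.87 and 1.01, ZNF267 by 0.81 and 1.17 and ZNF184 by 0.97 and 0.80. On the lower side were the stathmin gene STMN3 at -0.93 and -1.22, FAHD2B at -0.93 and -0.84, ANGPTL4, an inhibitor of lipoprotein lipase, at -0.80 and -0.94, TMEM64 at -0.79 in each line and MICB at -0.72 and -0.95. TRIAP1 stood at -0.79 and -0.70, NFATC1 at -0.66 and -1.01, the kinase gene MAP3K14 at -0.66 and -0.80, BAMBI at -0.66 and -0.73 and ITPKA at -0.65 and -0.79. As means over their probe sets, MESD stood at 0.46 and 0.55, GPNMB at 0.40 and 0.43, FAHD2B at -0.15 and -0.48 and MAP3K14 at -0.42 and -0.44, in Caco-2 ZNF572 at 0.45, NFATC1 at -0.32 and STMN3 at -0.34, and in HCT116 SEMA3A at 0.61 and ZNF84, with 1 of its 2 bright probe sets higher, at 0.45. STMN3 stood at -0.18 and -0.45 with _x_at and _s_at probe sets left out, and in Caco-2 turned to 0.05 with 16 added on the linear scale; TRIAP1 has no probe set of another kind. At 1.5-fold, 47 genes were higher in both lines, where independent lists give 8.95, and 17 were lower, where they give 6.79. Across the 9855 genes, which are not independent replicates, the differences of the lines had a Pearson r of 0.17 and a Spearman rho of 0.14, and the lines share no control array.

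No gene passed the test of a shared effect. In the limma fit over 4 arrays with cell line as a block, 11165 genes were tested, the smallest adjusted p was 0.769, and 670 genes had an unadjusted p under 0.05 where chance gives 558.2. For XRCC4 the fitted difference was 1.14 with a standard error of 0.17 and a limma adjusted p of 0.769, and for SEMA3A 1.16 with a standard error of 0.18 and the same adjusted p. With the values as deposited, no gene list held a member past the test, over all genes or adjusted over the list alone, where the smallest adjusted p was 0.058 among histone genes. The fit had 1 residual degree of freedom, and after quantile normalization 44 genes were higher and 38 lower, and after the loess correction 82 and 51. All 82 genes called after quantile normalization were among the 133 called after the loess correction, and they included 15 of the 20 genes named above for both lines. Members of 7 lists passed after both corrections, namely HMGA2 of the BORIS targets, SPA17, the p53 targets GDF15, TRIAP1 and PERP, SLC2A1, ANGPTL4, CCND1, SMAD6 and TNRC6A, and ACTA2, H2BC5 and SKIL passed after the loess correction alone. The prior degrees of freedom were then 157.58 and infinite, so a gene's own disagreement between lines counted for little or nothing. A call after these corrections therefore does not show an effect in both lines. SMAD6 was lower by at least 1.64 in HCT116 but stood at 0.16 in Caco-2 by the probe set used. Of its 3 bright probe sets in Caco-2, 1 was higher. TUBA1A, also called after both, stood at 1.56 in Caco-2 and 0.11 in HCT116.

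**Figure D4:**
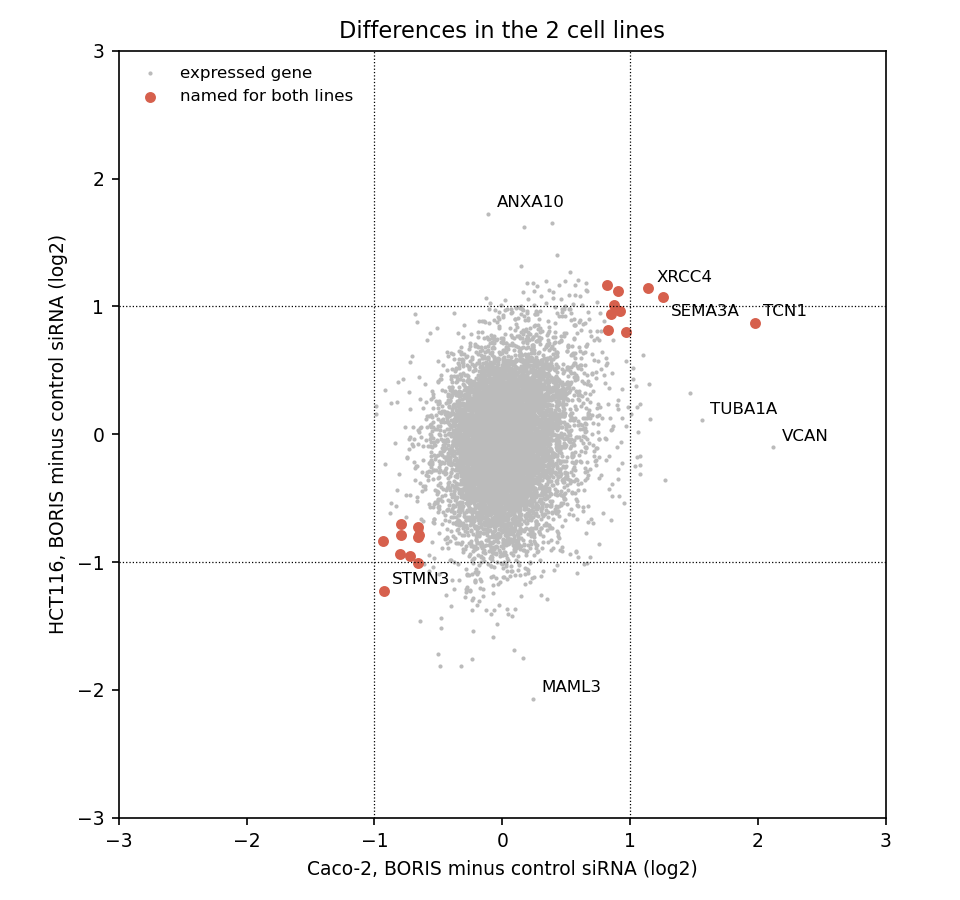
Log2 difference, BORIS minus control siRNA, in Caco-2 (horizontal axis) and HCT116 (vertical axis) for the 9855 genes expressed in both lines. Dotted lines mark 2-fold, and red points are the 20 genes named for both lines, with values at background drawn as deposited. XRCC4 and SEMA3A are the 2 points beyond 2-fold on both axes.

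The size of the difference between siRNAs was also set side by side in the 2 lines. No gene was at 2-fold or more in opposite directions. The cytokine gene CXCL8 was higher by 0.71 in Caco-2 and stood at -0.69 in HCT116, and TNRC6C, a gene of the small RNA silencing machinery, at 0.59 and -0.96. The difference in HCT116 was above that in Caco-2 by 2-fold or more for 43 genes and below it for 206, with 75 and 135 after quantile normalization, 22 and 64 with the mean of all probe sets of a gene, 18 and 117 with 16 added on the linear scale and 180 and 320 without a filter, and 137 below among genes whose bright probe sets share a direction. These are values without a test, since the interaction uses the last degree of freedom, and as the mean of its probe sets TNRC6C stood at 0.15 and -0.21.

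The difference between the cell lines came from the same fit. By the probe set used for each gene, all genes named here but S100P lay below background in the other line, GPX2 and TSPAN8 on 1 of its 2 arrays and the rest on both. Another probe set did reach the array median there for 2 of them, TM4SF1 (1 of 4 probe sets, in HCT116) and ANO1 (1 of 3, in Caco-2). Their lower bounds below hold for the probe set used. LYZ, the lysozyme gene, was higher in Caco-2 by at least 8.06 (limma adjusted p = 5.66e-06 for the values as deposited, not for the bound). Further bounds were 6.76 for TM4SF1, 6.58 for MMP7 and 6.18 for the galectin gene LGALS4. Those of AKR1C1, TM4SF4 and PRTFDC1 were 5.76, 5.40 and 4.65. The lower bound was 8.05 for GPX2 and 7.20 for TSPAN8, and the HCT116 minus Caco-2 difference was -6.96 for S100P. BEX3 was higher in HCT116 by at least 6.93 (limma adjusted p = 5.66e-06, again for the values as deposited). Further bounds were 6.92 for ADIRF, 6.81 for GTSF1, 6.31 for the galanin gene GAL and 6.27 for the cancer-testis antigen gene MAGEB2. Those of BNIP3 and ANO1 were 5.56 each, and those of ELOVL5, TMSB15A and BEX2 were 5.43, 5.33 and 4.58. Of the 17 enterocyte differentiation genes tested, 13 were higher in Caco-2 and 1 in HCT116 over all genes, and 14 and 1 adjusted over the list alone. Of 28 epithelial genes, 12 were higher in Caco-2 and 3 in HCT116, and 15 and 3 adjusted over the list alone. Of 36 p53 target genes, 25 were higher in HCT116 and 1 in Caco-2, and 27 and 1 adjusted over the list alone. In all, 2161 genes were higher in HCT116 and 2212 in Caco-2. The 2 arrays of each line differ in siRNA and nothing in the labels says that they came from separate cultures of the line's stock, so these p-values measure the spread between these arrays.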

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

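The tests of spike-in amount, RNA integrity and the loess correction reported here were chosen after the result was seen; the tests of the second probe set and of gene length were set before it.

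Control probe sets outside the comparisons differed between arrays. The 24 poly-A spike-in probe sets, RNAs added before labelling, were higher by a median of 0.88 (SD 0.20 across probe sets) on the HCT116 array with BORIS siRNA than on the HCT116 control array, and all 24 were higher. The 18 hybridisation controls, added after labelling, were higher by a median of 0.39, again all of them. In Caco-2 the same medians were -0.084 and 0.002. The HCT116 control array also lay above the Caco-2 control array, by 0.76 and 0.42.

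The excess of lower genes in HCT116, 154 against 62, lies between the same 2 HCT116 arrays. For the 79 lower genes with a second bright probe set, noise of single probe sets is argued against, since that probe set was lower for 72, or 91.1%. Its median difference was -0.821. The other lower genes had no second bright probe set and were not covered. With the mean of all probe sets of a gene, 55 genes were lower and 39 higher, so the size of the excess depends on the probe set chosen. A bias with intensity stays open, since lower genes outnumbered higher ones by 92 as deposited, by 28 after the loess correction and by 28 after quantile normalization, but these corrections also remove an effect of the siRNA that goes with expression. Less RNA in the labelling reaction may raise the spike-ins (0.882) but cannot be told apart from an effect of the siRNA, because 1 array holds both. RNA degradation and a loss of long transcripts also stay open: the difference between 3-prime and 5-prime control probe sets moved by at most 0.131 over 3 transcripts, too few to decide, and the rho of the difference with genomic length was -0.104; an effect of BORIS siRNA in HCT116 remains open too, untested.

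CXCL8 differed in opposite directions in the 2 lines, 0.708 in Caco-2 and -0.694 in HCT116, with 3 of 3 bright probe sets on each side. TNRC6C stood at 0.594 in Caco-2 and -0.957 in HCT116. The median of oxidative phosphorylation genes was -0.071 in Caco-2 and 0.153 in HCT116. None of these differences between lines was tested.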

How the results depend on the processing

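No expressed named gene at 2-fold or more, and no named line difference, turned its direction under the alternatives that gave it a value. Smaller differences did, such as STMN3 in Caco-2 from -0.93 to 0.05 with 16 added on the linear scale. Leaving out arrays in turn was not possible with a test, since each group holds 1 array and 3 arrays leave 0 residual degrees of freedom. The counts of the line difference, of lists that stood apart in each line and the limma counts without trend (0) and without the cell line block (0) stayed within 1.5 times. The cause of the shifts below was not tested, apart from those that follow from the size of change counted. With the mean of all probe sets, 22 genes were higher in Caco-2, 39 higher and 55 lower in HCT116 and 1 higher in both lines. With 16 added on the linear scale, which damps dim probe sets, the counts were 16 higher and 1 lower in Caco-2, 23 higher and 85 lower in HCT116, and 1 higher in both. At 1.5-fold, 289 were higher and 118 lower in Caco-2, 464 higher and 976 lower in HCT116, and 47 higher and 17 lower in both. At 3-fold, 6 were higher and 0 lower in Caco-2, 6 higher and 13 lower in HCT116, and 0 higher in both. Without a filter, 9 were lower in Caco-2, 5 higher and 1 lower in both, and Pearson's r between lines was 0.0865; with the olfactory receptor filter, 1 was lower in both. Quantile normalization gave 98 higher genes in HCT116. Genes past the limma test for the shared effect numbered 44 higher and 38 lower after quantile normalization and 82 and 51 after the loess correction, where the prior degrees of freedom were 157.58 and infinite in place of 5.49; 0 passed under the other settings. The effect was above that in Caco-2 by 2-fold or more in HCT116 for 180 genes without a filter, 22 with the mean of probe sets, 75 after quantile normalization and 18 with 16 added, and below it for 320, 64, 135 and 117. Keeping genes whose bright probe sets share a direction, an alternative chosen after the data had been seen, left 137 below. Other settings ended 6 list calls and gained 15. Of the siRNA differences of named genes under other settings, 115 were counted as moved and 2085 were not. Each is a difference between 1 array and 1 array with no replicate spread, so these counts do not measure error. Signal over background limits 15 of the 42 higher and 1 of the 5 lower genes in Caco-2, and 11 of the 62 higher and 32 of the 154 lower genes in HCT116, to a lower bound. With values at background raised to that level, also chosen after the data had been seen, 29, 4, 54 and 139 of these genes were at 2-fold or more, and no list call was ended or gained.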

Other observations

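The tests of gene length in Caco-2, and of the length trend for zinc finger genes, were chosen after those patterns were seen; the tests of chance and cross-hybridisation for zinc finger genes and of small RNAs were set before their results.

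Zinc finger genes with ZNF symbols were higher as a family in both lines. In Caco-2, 195 of 278 expressed ZNF genes were higher with BORIS siRNA, with a median of 0.16, and in HCT116 145 of 251, with a median of 0.066. The direction held under quantile normalization, with medians of 0.13 and 0.14, and after the loess correction, with medians of 0.18 and 0.13. ZNF681, ZNF615, ZNF572, ZNF84, ZNF267 and ZNF184 are members, and without these named genes the medians were 0.16 and 0.062. A random draw of genes of like expression is argued against, since the lower of the 2 percentiles was 99.99. Members of a family can vary together between arrays, and the random lists do not carry such shared variation. Without replicate arrays, variation of the whole family between arrays therefore stays open. Cross-hybridisation is argued against, since at least 88.4% of the median was kept without _x_at and _s_at probe sets. A trend with gene length is argued against too, since at least 107.3% was kept once that trend was removed. The GC content of the probes of these genes was not analysed here and stays open, as does an effect of BORIS siRNA. In Caco-2 the background probes of the array differed with their GC count, as given below for gene length. The family may therefore be higher in Caco-2 for a technical reason. The background probes do not settle this for HCT116, where a technical reason stays open too.

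Long genes were higher in Caco-2. The difference between siRNAs had a Spearman rho of 0.301 with genomic length across 10389 expressed genes, which are not independent replicates. With the genes split into 4 equal groups by length, the shortest had a median of -0.083 and the longest, from 67.6 kb, one of 0.11. The Caco-2 list medians of oxidative phosphorylation (-0.071), MYC (-0.060) and chromatin genes (0.15) were of similar size. So were those of cholesterol synthesis (0.15), NRF2 (-0.11) and enterocyte genes (-0.14), and interferon-stimulated genes stood at -0.20. Random lists were not matched on length, so a part of length in these calls was not tested. In HCT116 the rho was -0.104 and the longest group had a median of -0.13. Lower expression of long genes is argued against, since the partial rho given mean expression was 0.303, and so is cross-hybridisation, with a rho of 0.293 without _x_at and _s_at probe sets. GC content, which goes with gene length, was not analysed here for genes and stays open. The background probes of the array carry a GC count in their names. Their Caco-2 difference was -0.011 at GC05, -0.112 at GC16, -0.142 at GC21 and 0.008 at GC24. In HCT116 the same probes stood at 0.053, 0.022, 0.062 and 0.036. At the ends of the range, GC03 and GC25 stood at -0.0815 and -0.0737 in Caco-2 and at 0.317 and -0.092 in HCT116. The difference between the lines was not tested.

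Small nucleolar and Cajal body RNAs were tested as a class in HCT116 because SCARNA14 and SNORA12 were among the higher genes named. The 14 expressed members had a median of 0.21, 11 were higher, and the median lay at percentile 96.15, below the highest 2.5% of random lists, and between 93.84 and 96.14 with any 1 member left out. The class did not stand apart in these arrays.

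ACTB, often used as a reference gene, stood at -0.48 in HCT116 and -0.02 in Caco-2, POLR2A at -0.88 and -0.22 and B2M at 0.41 and 0.03.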
